A study of Rattus norvegicus with 16 samples.

How the data were processed

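Gene expression was measured on 16 Clariom S rat arrays, a microarray format that reports a signal for each annotated transcript cluster. The deposited values were on a log2 scale, and per the submitters' processing notes they were made with the Transcriptome Analysis Console, whose version was not given. The normalization method and the background correction were not given in the sources used here. The deposited tables printed 2 decimals, held no control probe sets, and a pair of them carried the same values for every sample (largest difference 0). The 16 array medians lay between 5.87 and 5.95, so the columns were used as deposited, with no further scaling and no filter on dim probes.

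The tables held 23188 transcript clusters, of which 21498 carried 1 gene symbol, 1673 carried several and 13 carried none. A spreadsheet had turned 27 symbols into dates, and 23 of these were restored while 4 were left unnamed. There were 20666 distinct symbols, of which 16238 matched a current RefSeq rat symbol, 2013 matched a synonym and 2415 were not found. For the 774 symbols with more than 1 cluster, the cluster with the highest mean over the 16 arrays stood for the gene.

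A linear model with 8 group means was fitted to all 16 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 8 residual and 9.21 prior degrees of freedom). The moderated test of limma was two-sided, its p was adjusted by Benjamini-Hochberg over the 23188 clusters within each of 13 contrasts, and a difference was called at an adjusted p under 0.05. The contrasts compared CD103- cells with cDC2, cDC1 and macrophages within each organ, cDC2 with cDC1 within each organ, each of the 4 populations between thymus and spleen, and the CD103- to cDC2 difference between the organs (the interaction, thymus minus spleen). Differences are given in log2 units with the model's standard error (SE), and levels as the mean ± SD of the 2 arrays of a group.

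There were 26 gene lists, drawn up before the data were examined. They covered cDC1, cDC2, cDC2A, cDC2B and DC3, pan conventional DC, plasmacytoid DC, monocyte and macrophage markers. They also covered MHC class II presentation, maturation and costimulation, cytokines and chemokines, pattern recognition receptors, Fc and complement receptors, lysosome, efferocytosis and lipid efflux, iron and haem recycling, cell cycle and the interferon response. The remaining lists held markers of T cells and thymocytes, B cells, NK cells, erythroid cells, neutrophils, platelets, and epithelial and stromal cells, and genes of RNA stress and dissociation. Some lists shared genes, and 13 of 21 monocyte markers, 10 of 22 macrophage markers and 12 of 15 cDC2B and DC3 markers stood in another list as well.

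Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 26 lists of a contrast, and again with the correlation estimated from the data. With fry, the directional p asks whether a list's genes move on balance one way, and the mixed p whether they change in either direction. Neither p of fry compares a list with other genes. Signatures of 100 called genes with the largest log2 differences were taken from the other populations in one organ and tested in the CD103- contrasts of the other organ, so that no array served both steps.

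Genes named in the text followed a rule fixed before the data were examined. It took 25 fixed genes whether called or not, the 8 genes per direction with the largest log2 difference between CD103- cells and cDC2 in each organ, and the 10 per direction called in both organs. For the other contrasts it took 6 genes per direction, and for each list up to 4 called members per direction. Apart from the fixed genes and the list members, a named gene was called and every array of one group lay above every array of the other, and clusters without a proper symbol were passed over. Itgae, Sirpa and Cd163 encode, or are bound by, the antibody targets used for the sort, so their values are checks.

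The contrasts, lists, tests and alternative settings were fixed before the data were examined, and the comparison with olfactory receptor genes as a background level was chosen afterwards. So was the rule that a log2 difference from a group whose mean lay below their 95th percentile of 5.73 is given only as a bound (at least, or below), which is the distance of the other group from 5.73 and has no SE. Interactions were not bounded in this way. The alternatives were array weights, a fit to only the arrays of the groups compared, a filter on dim probes (5.91, keeping 13566 clusters), median centring, quantile normalization, the replicate number as a block, eBayes with trend and robust, a change of at least 2-fold, an estimated inter-gene correlation, and leaving out each array in turn.

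The steps were tested on simulated data with 200 changed genes in each of 10 runs. At a log2 change of 1, 40.0% of the changed genes were found in the thymic CD103- to cDC2 contrast, 34.3% in the splenic contrast and 8.80% in the interaction. At a log2 change of 2 the shares were 92.4%, 94.0% and 70.0%, and at 4 they were 99.2%, 99.7% and 97.7%. False calls averaged 8.5, 7 and 6.4 per run, and the shifted list was found in 10 of 10 runs of each contrast. The simulated noise was independent between genes, whereas the data gave estimated correlations of 0.316 for macrophage and 0.609 for B cell markers. The runs therefore do not show how often camera falsely calls lists of correlated genes. The data also gave far more calls (2377 in the thymic and 2092 in the splenic contrast) than the 200 changed genes of a run. The Benjamini-Hochberg cutoff depends on the share of changed genes, so recovery and false calls may differ in the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.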

Results

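Dendritic cells (DCs) and macrophages were sorted from the thymus and spleen of male Lewis rats, and the RNA of each sort was read on a rat gene expression array. Conventional type 1 DCs (cDC1) were sorted as MHC class II+ CD103+ CD172a- cells, type 2 DCs (cDC2) as CD103+ CD172a+ cells, and a further DC-like population as CD103- CD45R- CD172a+ cells, called CD103- cells here. Macrophages were sorted with HIS36, an antibody to rat Cd163. Each of the 8 groups (4 populations in each organ) held 2 replicate arrays, and this number limits the precision of every value. The labels did not say whether the replicates came from separate animals, so the p-values measure only the spread between these samples. Deviations of replicate 1 from the group mean correlated by over 0.1 across clusters in 4 of 28 pairs of groups. These were the pairs of splenic DC groups (0.155 to 0.182) and thymic cDC2 with CD103- cells (0.166). With the replicate number as a block, 6 of 1590 gene calls were lost and 1 gained, and 3 list calls were gained. The block fitted a single shift between replicate numbers for all groups. It cannot show what a pairing within the DCs of an organ would change. Spleen DCs were enriched on a density gradient, thymic DCs with MHC class II beads and macrophages with CD11b/c beads. The isolation method therefore changed with the organ for DCs and with the cell type for macrophages.

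Array medians were alike (5.87 to 5.95), with lowest values of 2.50 to 2.70 and highest values of 19.78 to 19.91. Across genes, the root mean square log2 difference within the 8 replicate pairs was 0.373 to 0.457, with Pearson's r of 0.9894 to 0.9936 (genes are not independent replicates). Olfactory receptor genes, 1296 clusters of odorant receptors of the nose, had a median of 4.14 and a 95th percentile of 5.73. All group means of 39.38% of the clusters lay below that percentile. It is called background in what follows, and differences from groups there are given as bounds. The sort markers served as checks. Itgae, which encodes CD103, was 13.66 ± 0.18 in thymic cDC2 and 6.02 ± 0.16 in thymic CD103- cells, with 13.27 and 7.93 in the spleen. Sirpa, which encodes CD172a, was 18.71 and 18.12 in thymic CD103- cells and cDC2, and 18.30 and 18.06 in the spleen. It exceeded its cDC1 level by 9.64 in thymic CD103- cells and by 9.74 in splenic ones. Cd163, the HIS36 antigen, was lower in CD103- cells than in macrophages (-8.51 ± 0.49, adjusted p = 3.14e-10 in the thymus and -9.69 ± 0.49, adjusted p = 7.45e-11 in the spleen).

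The principal component plot of all clusters set macrophages apart from DCs along its main axis, which carried 52.32% of the variance. Macrophage arrays lay at 139.43 to 165.99 and DC arrays at -78.31 to 0.19. Among the DCs, the thymic CD103- arrays (-7.00 and 0.19) and the splenic ones (-32.39 and -27.88) lay closest to the macrophages. The next axis carried 15.46% and held the cDC1 arrays at 68.01 to 76.43. As the root mean square difference of the group means over all clusters, in log2 units, thymic CD103- cells lay 0.68 from cDC2, 1.02 from cDC1 and 1.28 from macrophages. In the spleen the distances were 0.69, 1.00 and 1.30. The cDC2 to cDC1 distances were 0.85 in the thymus and 0.90 in the spleen.

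**Figure D1:**
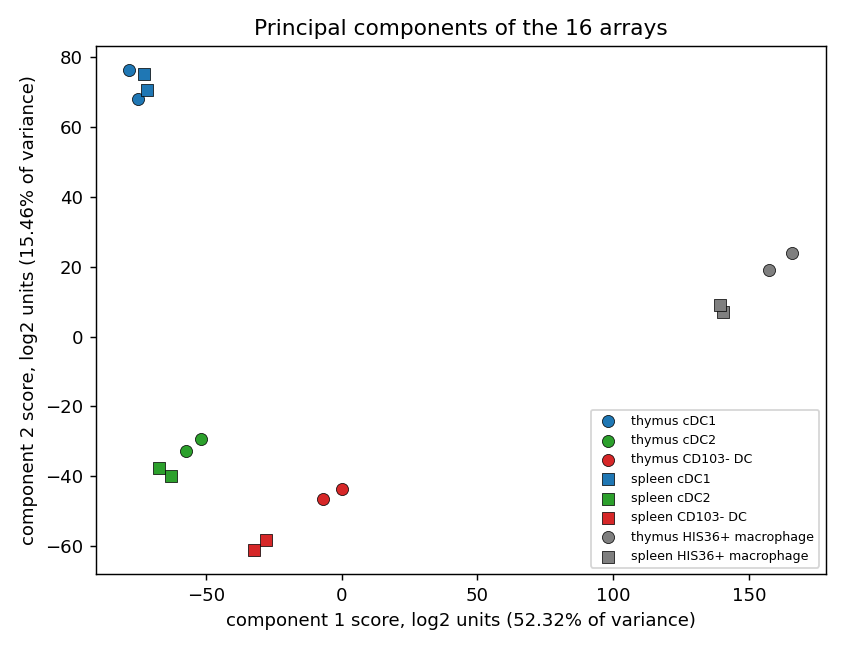
Scores of the 16 arrays on principal component 1 (x axis, 52.32% of the variance) and 2 (y axis, 15.46%), coloured by population with organs as different symbols. Macrophage arrays sit at 139.43 to 165.99 on the x axis, and DC arrays at or below 0.19.

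The first question was how CD103- cells differed from CD103+ cDC2 of the same organ. In the thymus, CD103- cells were higher in many genes of monocytes and macrophages. Fcnb, a secreted pattern recognition lectin of the monocyte lineage, was 17.35 ± 0.38 in CD103- cells and 7.88 ± 0.52 in cDC2 (log2 difference 9.46 ± 0.39, adjusted p = 6.31e-11). Cd14, the co-receptor for lipopolysaccharide, was 15.61 ± 0.13 against 9.70 ± 0.17 (5.90 ± 0.31, adjusted p = 1.28e-09). The chemokine receptor Ccr2, used by monocytes to leave the bone marrow, was higher by 4.18 ± 0.56 (adjusted p = 4.92e-05). Among the largest differences were the membrane collagenase Mmp14 (at least 6.79), the cytokines Il1a (6.85) and Osm (5.95), fibronectin Fn1 (6.74), the apolipoprotein Apoc1 (at least 5.48) and complement C3 (6.30). The phagocytic receptor Mertk was higher by 3.81, the complement component C1qa by 3.73, the lectin Clec10a by 3.07, the fractalkine receptor Cx3cr1 by 3.19 and the growth factor receptor Csf1r by 1.38.

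In the same thymic contrast Itgae was lower (-7.64 ± 0.23, adjusted p = 7.81e-13). Lower along with it were Il22ra2, a soluble inhibitor of interleukin 22 (-8.15 ± 0.36, adjusted p = 1.5e-10), the tight junction gene Cldn1 (-7.73), the growth factor Bmp6 (-5.72), the channel Tmem63c (-4.99 or below) and the lysophosphatidic acid receptor Lpar3 (-4.73 or below). The nonclassical MHC gene RT1-M5 (-4.69 or below), the potassium channel Kcnh5 (-4.55 or below) and the macrophage scavenger receptor Cd163 (-3.29, adjusted p = 0.000138) were lower as well. Flt3, the cytokine receptor on which conventional DCs depend, was 10.30 ± 0.25 in CD103- cells and 12.55 ± 0.16 in cDC2 (-2.25 ± 0.26, adjusted p = 7.04e-06). Zbtb46, a transcription factor of conventional DCs, was lower (-1.37, adjusted p = 0.00461), a call lost without thymus CD103- replicate 2 (-1.16, adjusted p = 0.0729). Irf8 (0.87, adjusted p = 0.084), Irf4 (-0.45, adjusted p = 0.397), Clec9a (adjusted p = 0.329), Sirpa (0.59, adjusted p = 0.519), Ccr7 (-1.12, adjusted p = 0.229), Cd86 (0.51), Ptprc (-0.14) and Esam (0.66) did not pass. Tbx21 and Cd209a lay below background in both groups. Of the 23188 clusters, 1238 were higher and 1139 lower in thymic CD103- cells, 1715 of these 2377 by at least 2-fold. Without thymus cDC2 replicate 1 the calls numbered 1520, the lowest count with an array left out.

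In the spleen the same kind of genes stood out. Cd14 was 14.70 ± 0.69 in CD103- cells and 5.88 ± 0.53 in cDC2 (8.82 ± 0.31, adjusted p = 1.04e-11), and Fcnb was 15.82 ± 0.31 against 7.46 ± 0.04 (8.36 ± 0.39, adjusted p = 1.38e-10). Ly6c, a surface antigen of monocytes, was higher by 7.10 ± 0.25 (adjusted p = 1.04e-11) and Ccr2 by 4.32. The chemokine Cxcl11 (at least 7.05), the inducible nitric oxide synthase Nos2 (at least 7.86), the chemerin receptor Cmklr1 (at least 6.95), guanine deaminase Gda (at least 7.66), the oxidised lipoprotein receptor Olr1 (7.63), the phagosomal metal transporter Slc11a1 (at least 6.52) and the transcription factor Tfec (7.34) had the other largest differences. The high-affinity IgG receptor Fcgr1a was higher by 4.91, Clec12a by 3.74, Mertk by at least 3.02, C1qa by 2.67 and Irf8 by 1.87.

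Lower in splenic CD103- cells were the apoptosis inhibitor Faim2 (-6.62 ± 0.39, adjusted p = 2.28e-09), Itgae (-5.34 ± 0.23, adjusted p = 4.75e-11) and Il22ra2 (-5.12). So were the chemokine receptors Xcr1 (4.08 ± 0.11 against 9.30 ± 0.74 in cDC2, -3.56 or below, adjusted p = 7.6e-08) and Cxcr3 (-4.53), the Notch regulator Dtx1 (-3.27 or below), and the Notch target Hes1 (-2.76). Clec9a, a receptor for dead cells typical of cDC1, was lower (-3.32), as was Zbtb46 (-2.02, adjusted p = 0.000137). Flt3 was lower (-1.05, adjusted p = 0.0122), a call lost without spleen cDC2 replicate 2 (-0.81, adjusted p = 0.162), CD103- replicate 1 (adjusted p = 0.0617) or CD103- replicate 2 (adjusted p = 0.0722). Irf4 was lower (-0.97, adjusted p = 0.031), a call lost without spleen CD103- replicate 2 (-0.63, adjusted p = 0.316) or either cDC2 replicate (adjusted p = 0.123 and 0.125). Clec10a was higher by 1.53 (adjusted p = 0.00414) and lost its call without spleen cDC2 replicate 1 (adjusted p = 0.0921). Csf1r (1.14), Cx3cr1 (1.13) and Esam (0.96) were called too, but without spleen cDC2 replicate 2 their adjusted p was 0.0742, 0.203 and 0.265, and without CD103- replicate 1 it was 0.0562, 0.148 and 0.126. Without CD103- replicate 2 it was 0.0567 for Csf1r and 0.103 for Esam. Cd163 (adjusted p = 0.41), Cd86 (0.56, adjusted p = 0.192), Sirpa (0.25), Ptprc (0.27) and Ccr7 (-0.07) did not pass. Tbx21 and Cd209a lay below background here too. In all, 1115 clusters were higher and 977 lower in splenic CD103- cells, 1574 of the 2092 by at least 2-fold. Without spleen cDC2 replicate 2 the calls numbered 1388.

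**Figure D2:**
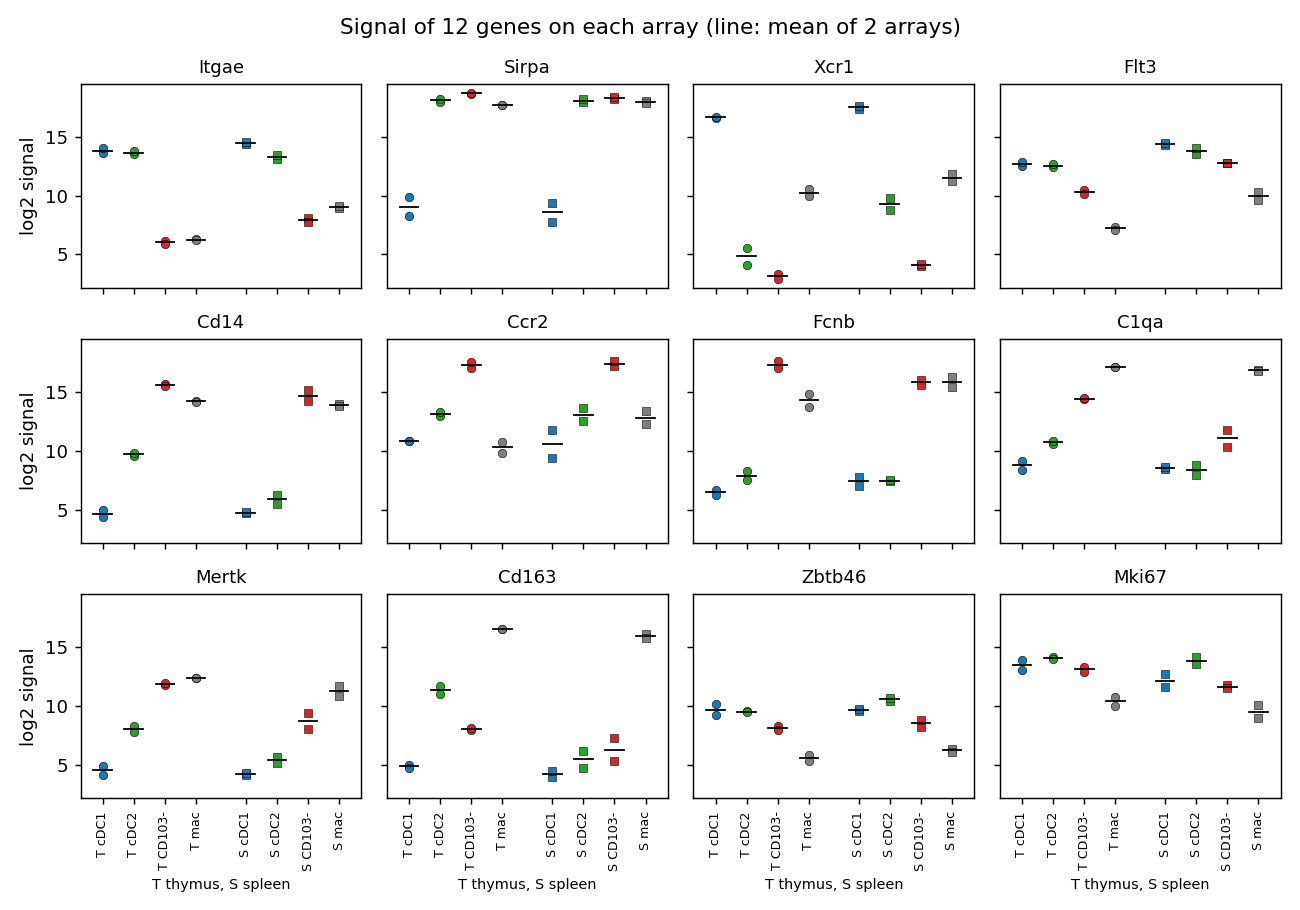
Log2 signal of 12 genes (y axis) on each array of the 8 groups (x axis), with points for the 2 arrays. Fcnb, Cd14, Ccr2 and C1qa lie higher in CD103- cells than in cDC2 of the same organ on both arrays, and Itgae lies lower.

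The organs shared many of these differences. Called in the same direction in both organs were 898 clusters, with 572 higher and 326 lower in CD103- cells against 59.5 and 48 that independence would give. A further 50 were called in opposite directions, against 106.9 under independence, and the count was 22 with spleen CD103- replicate 1 left out. The counts under independence were taken over all clusters, including the 39.38% with all group means below background. Both contrasts also used the same error for a gene. Each of these can raise the overlap, so the excess of shared calls is not a measure of its size. Across genes, the thymic and splenic log2 differences had a Pearson's r of 0.517 (genes are not independent replicates). Higher in both organs were Fcnb, Cd14, Il1a, Fn1 (6.74 in the thymus, 5.62 in the spleen), Tfec (4.98, 7.34), Ly6c (4.86, 7.10), the transmembrane glycoprotein Gpnmb (4.84, 4.80), Rtp3 (4.69, 5.36) and the transcription factor Prdm1 (4.65, 4.82). Lower in both were Itgae, Il22ra2, Gpr82 (-4.33 or below, -4.13), Lpar3 (-4.73 or below, -3.39 or below), Bmp6 (-5.72, -3.48), the adhesion molecule Epcam (-3.93, -2.81), the prion protein gene Prnp (-3.51, -3.01), Septin1 (-2.93, -3.24), the inhibitory receptor Lair1 (-4.30, -2.73) and the prohormone convertase Pcsk1 (-3.09, -2.65). As the naming rule required, each of these genes lay on the same side on 2 of 2 CD103- arrays against both cDC2 arrays in each organ.

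**Figure D3:**
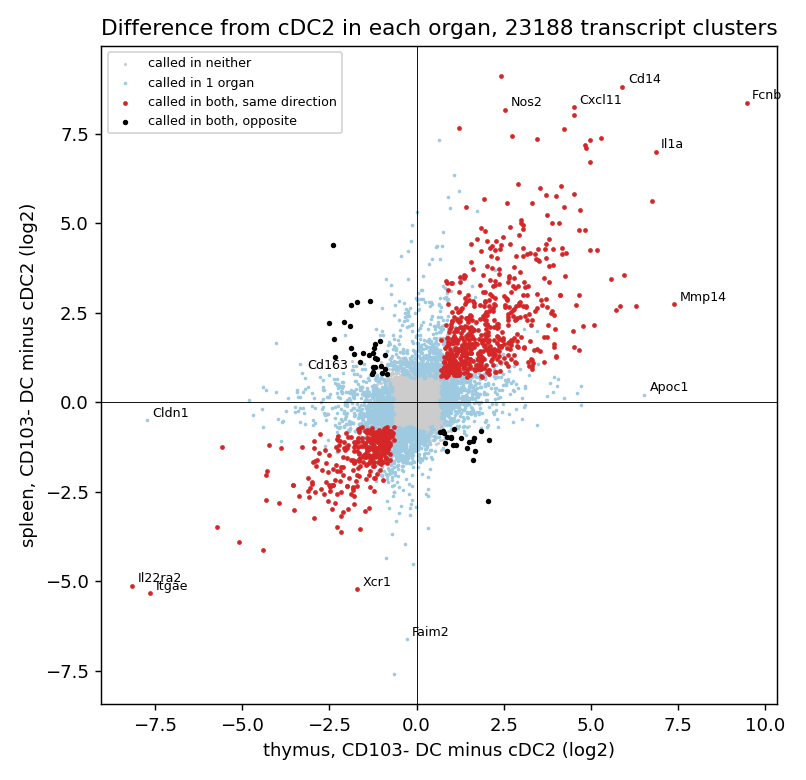
Log2 difference of CD103- cells minus cDC2 in the thymus (x axis) against the spleen (y axis), with a point per transcript cluster coloured by where it was called. Of the clusters called in both organs, 898 share their direction and 50 do not.

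Among the lists, monocyte markers were higher in CD103- cells of both organs. Of 21 members, 13 were higher and 1 lower in the thymus (16 and 1 adjusted over the list alone), and 13 higher and 0 lower in the spleen (13 and 0 adjusted over the list alone). With an estimated correlation the list kept its call (adjusted p = 0.000669 and 0.000576). Macrophage markers gave 14 higher and 1 lower of 22 in the thymus (15 and 1 adjusted over the list alone) and 15 higher and 1 lower in the spleen (15 and 1 adjusted over the list alone), and also kept their call (adjusted p = 0.0258 and 0.0177 with an estimated correlation). The cDC2B and DC3 markers, a list for the monocyte-like branch of cDC2, gave 9 higher and 1 lower of 15 in the thymus and 8 higher and 0 lower in the spleen (10 and 1 adjusted over the list alone, then 11 and 0 adjusted over the list alone), with adjusted p = 0.000669 and 0.000485 with an estimated correlation. These 3 lists overlap, so they are not separate evidence.

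Several lists of innate function rose with them. Interferon response genes gave 20 higher and 1 lower of 24 in the thymus (20 and 1 adjusted over the list alone) and 21 higher and 0 lower in the spleen (23 and 0 adjusted over the list alone), with Ifit2 at 4.13 and 6.05. Irf7 was higher too (at least 3.19 and 4.29), as was Mx1 in the thymus (3.81). Cytokines and chemokines gave 16 higher and 0 lower of 25 (18 and 0 adjusted over the list alone) and 17 higher and 0 lower (19 and 1 adjusted over the list alone), among them Ccl3 (4.24 and 5.46) and Cxcl9 (4.08 and 5.01). Pattern recognition receptors gave 12 higher and 0 lower of 19 (15 and 0 adjusted over the list alone) and 13 higher and 1 lower (15 and 1 adjusted over the list alone), with Tlr8 at 2.80 and 3.77 and Clec7a at 4.43 in the spleen. Fc and complement receptors gave 8 higher and 0 lower of 11 (8 and 0 adjusted over the list alone) and 6 higher and 0 lower (6 and 0 adjusted over the list alone), with Fcgr3a (at least 3.73) in the thymus and C3ar1 (at least 5.61) in the spleen. Lysosome genes gave 15 higher and 0 lower of 23 (19 and 0 adjusted over the list alone) and 13 higher and 0 lower (14 and 1 adjusted over the list alone), with the cholesterol carrier Npc2 at 3.09 and 3.37 and the protease Ctsd at 3.83 in the thymus. Efferocytosis and lipid efflux gave 12 higher and 2 lower of 21 (14 and 2 adjusted over the list alone) and 11 higher and 1 lower (12 and 2 adjusted over the list alone), with the sterol sensor Nr1h3 at 5.17 and 4.26 and the transporter Abca1 (4.25 and at least 3.12). All 6 lists kept their call in both organs with an estimated correlation, at an adjusted p between 0.000346 for interferon in the spleen and 0.0105 for efferocytosis in the spleen. Iron and haem recycling gave 8 higher and 3 lower of 12 in the thymus (8 and 3 adjusted over the list alone), where adjusted p = 0.00136 became adjusted p = 0.126 with an estimated correlation. In the spleen it gave 7 higher and 1 lower (9 and 2 adjusted over the list alone) and kept its call (adjusted p = 0.0172 with an estimated correlation).

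Genes of conventional DCs and of cell division were lower. Of 9 pan conventional DC markers, 5 were lower in the thymus and 6 in the spleen, with none higher (6 and 6 lower adjusted over the list alone), and the list kept its call (adjusted p = 0.0095 and 0.0172 with an estimated correlation). Dpp4, a surface peptidase, was lower in the thymus (-2.20), and Kmo, of tryptophan metabolism, in the thymus (-1.68) and the spleen (-1.83). Cell cycle genes were lower for 8 of 29 in the thymus and 16 in the spleen (17 and 24 adjusted over the list alone), with none higher. The proliferation marker Mki67 was 11.66 in splenic CD103- cells and 13.87 in cDC2 (-2.21), and the mitotic kinase Plk1 was lower there too (-1.89). The splenic cell cycle call held (adjusted p = 0.0172 with an estimated correlation) and the thymic one did not (adjusted p = 1.53e-09, and adjusted p = 0.0669 with an estimated correlation).

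The subset lists split further. General cDC2 markers gave 6 higher and 0 lower of 16 in the thymus (6 and 0 adjusted over the list alone; adjusted p = 0.00658 with an estimated correlation), and 3 higher and 1 lower in the spleen (3 and 2 adjusted over the list alone), where the list was not called (adjusted p = 0.253). The cDC2A markers gave 1 higher and 0 lower of 7 in the thymus (1 and 0 adjusted over the list alone; adjusted p = 0.638, with a median of -0.20 but a mean of 0.22 and an upward test) and 1 higher and 2 lower in the spleen (1 and 3 adjusted over the list alone). The splenic call for cDC2A markers was lost with an estimated correlation (adjusted p = 0.0155 against adjusted p = 0.0602 with an estimated correlation). Markers of cDC1 gave 4 higher and 5 lower of 15 in the thymus (5 and 6 adjusted over the list alone; adjusted p = 0.439). In the spleen they gave 2 higher and 6 lower (2 and 9 adjusted over the list alone), with Xcr1, Clec9a and the germinal centre gene Gcsam (-3.18 or below) lower, but without the call when correlation was estimated (adjusted p = 1.45e-05, and adjusted p = 0.0602 with an estimated correlation). Plasmacytoid DC markers gave 5 higher and 1 lower of 13 in the thymus (5 and 1 adjusted over the list alone; adjusted p = 0.0459, and adjusted p = 0.177 with an estimated correlation) and 6 higher and 1 lower in the spleen (7 and 1 adjusted over the list alone; adjusted p = 0.0114 with an estimated correlation).

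MHC class II presentation gave 3 higher and 0 lower of 14 in the thymus (4 and 1 adjusted over the list alone; adjusted p = 0.00616, and adjusted p = 0.177 with an estimated correlation), including RT1-DMa (1.49), and 3 higher and 1 lower in the spleen (3 and 3 adjusted over the list alone; adjusted p = 0.73). Maturation and costimulation gave 2 higher and 4 lower of 23 in the thymus (2 and 5 adjusted over the list alone; adjusted p = 0.095) and 6 higher and 0 lower in the spleen (7 and 1 adjusted over the list alone; adjusted p = 0.00143, and adjusted p = 0.295 with an estimated correlation). Ccl22, a chemokine of mature DCs, was lower in the thymus (-1.71) and higher in the spleen (2.81). Fscn1, an actin bundler of mature DCs, was lower in the thymus (-2.57), the costimulatory ligand Tnfsf9 was higher there by 2.08, and the adaptor Samsn1 was higher by 2.63 in the spleen.

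Calls among markers of other cell types between CD103- cells and cDC2 varied by list. Over all 23188 clusters, 2377 were called in the thymus and 2092 in the spleen. T cell and thymocyte markers gave 1 higher and 4 lower of 18 in the thymus (2 and 4 adjusted over the list alone; adjusted p = 0.0223, and adjusted p = 0.268 with an estimated correlation) and 2 higher and 1 lower in the spleen (2 and 1 adjusted over the list alone; adjusted p = 0.079). The higher thymic member was Cd8b (3.94), and the lower ones included Tcf7 (-1.79) and Cd28 (-1.73). B cell and erythroid markers had 0 members called by limma in either organ, also when adjusted over the list alone. With camera their list adjusted p ran from 0.359 to 0.945 and from 0.638 to 0.813. With fry their mixed adjusted p ran from 0.59 to 0.913. In the spleen the mean of the B cell markers rose from replicate 1 to 2 in cDC2 (7.111, 8.505) and in CD103- cells (7.581, 8.688). That spread widens the error of an unpaired comparison. NK cell markers gave 1 higher member of 9 in each organ (1 and 1 adjusted over the list alone; adjusted p = 0.945 and 0.0686, the thymic median of -0.12 against a mean of 0.02 and a downward test). Neutrophil markers gave 2 higher and 0 lower of 12 in the thymus (2 and 0 adjusted over the list alone; adjusted p = 0.0352, and adjusted p = 0.0902 with an estimated correlation) and 2 higher and 1 lower in the spleen (2 and 1 adjusted over the list alone; adjusted p = 0.0454, and adjusted p = 0.0832 with an estimated correlation). Platelet markers gave 1 higher member of 5 in the thymus and 0 in the spleen (1 and 0 adjusted over the list alone; adjusted p = 0.638 and 0.718). Epithelial and stromal markers gave 0 higher and 3 lower of 14 in the thymus (0 and 4 adjusted over the list alone; adjusted p = 0.0351, and adjusted p = 0.11 with an estimated correlation) and 1 higher and 2 lower in the spleen (1 and 4 adjusted over the list alone; adjusted p = 0.183). Genes of RNA stress and dissociation gave 5 higher and 0 lower of 16 in the thymus (8 and 0 adjusted over the list alone), a call lost on estimating correlation (adjusted p = 8.72e-05, and adjusted p = 0.158 with an estimated correlation). In the spleen they gave 2 higher and 1 lower (3 and 3 adjusted over the list alone; adjusted p = 0.813, with a median of -0.11 but a mean of 0.09 and a downward test). Leaving out an array also ended list calls. In the thymus the adjusted p became 0.41 for T cell and thymocyte markers without cDC2 replicate 2, 0.177 for epithelial and stromal markers without CD103- replicate 2, 0.12 for plasmacytoid DC markers without cDC2 replicate 1, 0.0968 for neutrophil markers without CD103- replicate 1 and 0.0522 for MHC class II presentation without cDC2 replicate 1. In the spleen it became 0.116 for neutrophil markers without cDC2 replicate 1 and 0.0651 for cDC2A markers without CD103- replicate 2. Of the 26 lists, camera called 19 in the thymus and 17 in the spleen, of which 11 and 13 held with an estimated correlation, and fry called 19 in each organ on its directional p.

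**Figure D4:**
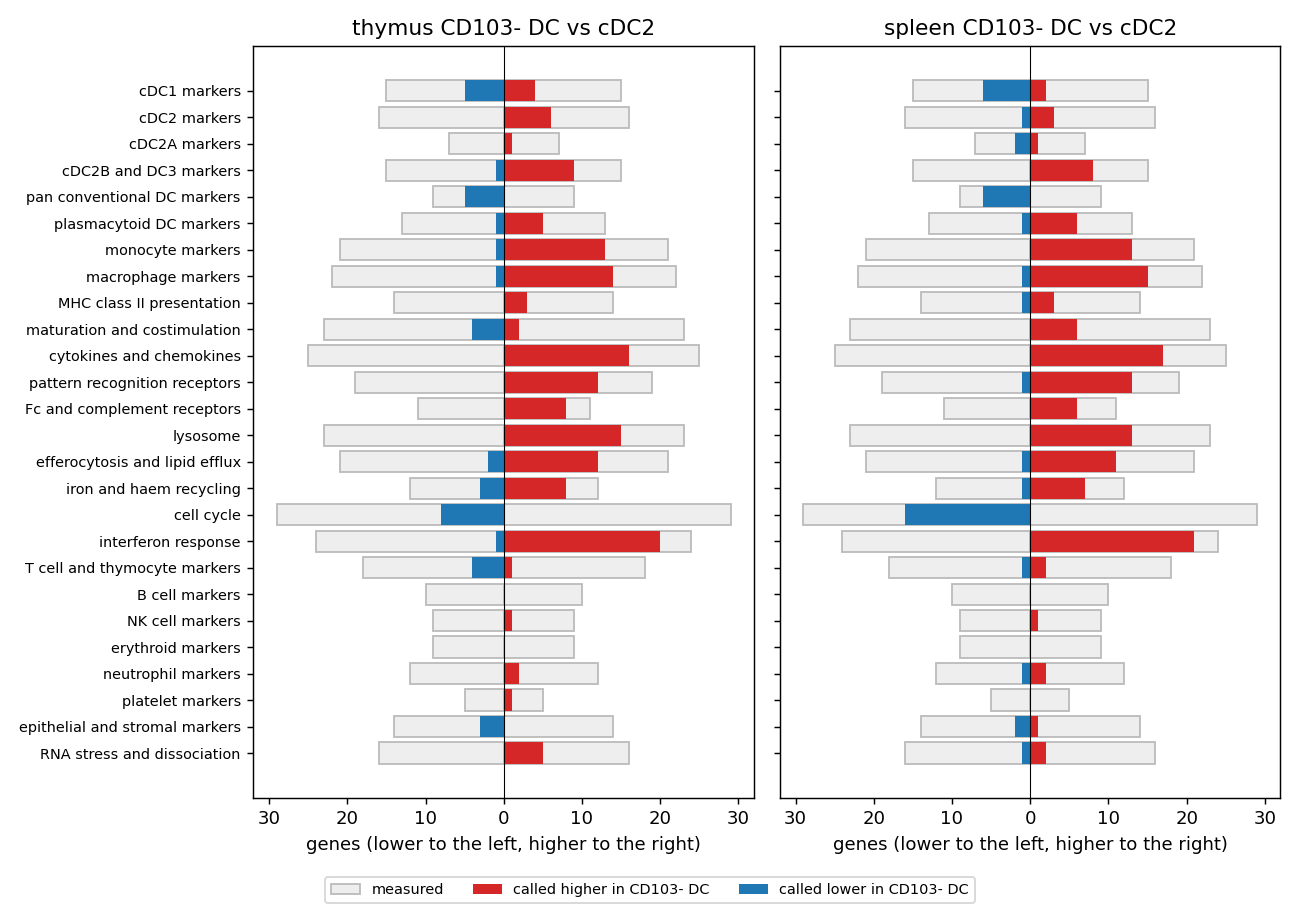
Number of genes (x axis) in each of the 26 lists (y axis), with measured members in grey and members called higher (red, to the right) or lower (blue, to the left) in CD103- cells than in cDC2, drawn for thymus and spleen. Interferon response genes reach 20 and 21 higher of 24.

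Whether the CD103- to cDC2 difference itself differed between organs was tested with the interaction. Of 823 called clusters, 332 had the more positive difference in the thymus and 491 in the spleen. More positive in the thymus were the differences of Apoc1 (6.31 ± 0.52, adjusted p = 1.86e-06), Mmp14 (4.65 ± 0.37, adjusted p = 1.74e-06), Faim2 (6.35), Hes1 (4.80), Cxcr3 (4.44), Xcr1 (3.52), Clec9a (2.74) and Cx3cr1 (2.06). Hes1 was higher in thymic CD103- cells (2.04) and lower in splenic ones (-2.76). Faim2, Cxcr3, Xcr1 and Clec9a were lower in splenic CD103- cells. In the thymus Clec9a was not called while Faim2, Cxcr3 and Xcr1 lay below background in both groups. Apoc1 did so in both splenic groups. More positive in the spleen were those of Cldn1 (-7.23 ± 0.59, adjusted p = 1.86e-06), the hyaluronan receptor Lyve1 (-6.80), the itaconate enzyme Acod1, printed as Irg1 on the array (-6.70), and Gda (-6.44). So were those of the gap junction gene Gjb2 (-5.70), Nos2 (-5.63), S100a4 (-5.31), Ccl22 (-4.52), Cd163 (-4.11), Cd14 (-2.92), Itgae (-2.30) and Fcgr1a (-2.22). At least 1 of the 4 group means of Apoc1, Mmp14, Faim2, Cxcr3, Xcr1, Clec9a, Cldn1, Lyve1, Gda, Nos2, S100a4, Cd163 and Mertk lay below background. The sizes of their interactions depend in part on background signal. Cd14 was higher in CD103- cells of both organs, with the wider gap in the spleen. Clec12a was called (-1.57, adjusted p = 0.0452), but only thymus CD103- replicate 1 could be left out without losing the call (adjusted p of 0.0852 to 0.209 without each of the other 7 arrays). Among fixed genes without a called interaction were Flt3 (-1.20, adjusted p = 0.0832), Clec10a (1.54, adjusted p = 0.0795), Irf8 (adjusted p = 0.285), C1qa (1.06, adjusted p = 0.379), Zbtb46 (0.66), Irf4 (0.52), Mertk (0.47), Csf1r (0.24) and Ccr2 (-0.14). Camera called 11 lists in the interaction and none (0 of 26) with an estimated correlation, where the lowest adjusted p was 0.144. With that correlation 3 lists passed unadjusted, and fry called 4 on its directional p.

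The next question was where CD103- cells stood between the other populations, asked with signatures defined in the opposite organ. Of 100 genes higher in macrophages than in DCs, 53 were higher and 4 lower in thymic CD103- cells than in cDC2 (adjusted p = 0.00135 with an estimated correlation), and 61 were higher and 1 lower in the spleen (adjusted p = 0.00621 with an estimated correlation). Of 100 genes higher in DCs than in macrophages, 4 were higher and 55 lower in the thymus (adjusted p = 0.00135 with an estimated correlation). In the spleen 10 were higher and 31 lower (adjusted p = 3.62e-05, and adjusted p = 0.248 with an estimated correlation). Of 100 genes higher in cDC1 than in cDC2, 35 were higher and 16 lower in the thymus (adjusted p = 4.6e-06, and adjusted p = 0.0811 with an estimated correlation) and 29 higher and 24 lower in the spleen (adjusted p = 0.133). Of 100 genes higher in cDC2 than in cDC1, 29 were higher and 30 lower in the thymus (adjusted p = 0.799) and 40 higher and 19 lower in the spleen (adjusted p = 1e-05, and adjusted p = 0.127 with an estimated correlation).

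Against cDC1, CD103- cells were higher in most genes of cDC2 and of macrophages. Of the 100 genes higher in cDC2 than in cDC1, 75 were higher and 6 lower in thymic CD103- cells, and 88 were higher and 1 lower in splenic ones (adjusted p = 9.05e-05 and 7.57e-05 with an estimated correlation). Of the 100 cDC1 signature genes, 8 were higher and 78 lower in the thymus and 1 higher and 80 lower in the spleen (adjusted p = 0.000192 and 0.000144 with an estimated correlation). The macrophage signature gave 68 higher and 1 lower in the thymus, and 69 higher and 2 lower in the spleen (adjusted p = 0.000192 and 0.00255 with an estimated correlation). The signature of DCs over macrophages gave 12 higher and 55 lower in the thymus (adjusted p = 0.00294 with an estimated correlation) and 20 higher and 41 lower in the spleen (adjusted p = 0.00261, and adjusted p = 0.33 with an estimated correlation). All 15 of the 15 fixed cDC1 markers were lower in both organs, over all genes and adjusted over the list alone (adjusted p = 0.00146 and 0.00116 with an estimated correlation). Xcr1, the receptor by which cDC1 meet T cells, was lower in the thymus (-10.92 or below, adjusted p = 9.94e-14) and in the spleen (-11.77 or below, adjusted p = 3.36e-13). Lower in both organs were Clec9a (-10.43 or below in the thymus, -11.40 in the spleen), Gcsam (-10.84 or below, -11.79 or below), the protease inhibitor Slpi (-12.96, -8.57), the adaptor Clnk (-7.55 or below, -8.19), and Irf8, a transcription factor that cDC1 require (-4.33, -3.94). Flt3 was lower too (-2.39, -1.65). Higher were Cd14 (at least 9.87 in the thymus, at least 8.96 in the spleen), Il1a (at least 10.24, at least 9.20) and Csf1r (at least 9.11, 8.30). Thymic CD103- cells also exceeded cDC1 in the urokinase Plau (at least 9.87), the complement gene C1qb (at least 9.23) and the phospholipase Pla2g2d (10.17), and splenic ones in the prostaglandin synthase Ptgs2 (8.85), the transcription factor Zeb2 (8.75) and Nos2 (at least 7.86). Monocyte markers gave 16 higher and 2 lower of 21 in the thymus (16 and 2 adjusted over the list alone) and 15 higher and 1 lower in the spleen (16 and 1 adjusted over the list alone), and macrophage markers 19 higher and 1 lower of 22 (19 and 1 adjusted over the list alone) and 14 higher and 1 lower (14 and 1 adjusted over the list alone). With an estimated correlation the adjusted p was 0.000776 and 0.00101 for monocyte and 0.00866 and 0.0466 for macrophage markers. The maturation list was lower in the thymus for 13 of 23 and higher for 2 (3 and 14 adjusted over the list alone; adjusted p = 7.09e-06, and adjusted p = 0.137 with an estimated correlation). In the spleen it was higher for 12 and lower for 1 (13 and 1 adjusted over the list alone; adjusted p = 4.37e-08, and adjusted p = 0.0917 with an estimated correlation). Pan conventional DC markers were not called in either organ (adjusted p = 0.941 and 0.857). Their medians of 0.60 and 0.69 stood against means of -0.01 and -0.22, with an upward test in the thymus and a downward one in the spleen. In total, 2007 clusters were higher and 2107 lower in the thymus, and 2001 higher and 2195 lower in the spleen.

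Against macrophages, CD103- cells were higher in most genes of DCs. Of the 100 genes higher in DCs than in macrophages, 90 were higher and 0 lower in thymic CD103- cells, and 85 were higher and 3 lower in splenic ones (adjusted p = 0.000384 and 0.0101 with an estimated correlation). Of the 100 macrophage signature genes, 6 were higher and 80 lower in the thymus and 1 higher and 95 lower in the spleen (adjusted p = 0.00131 and 0.00221 with an estimated correlation). The cDC2 signature gave 53 higher and 28 lower in the thymus (adjusted p = 0.00619, and adjusted p = 0.199 with an estimated correlation) and 35 higher and 39 lower in the spleen (adjusted p = 0.376). The cDC1 signature gave 31 higher and 27 lower in the thymus (adjusted p = 0.984) and 24 higher and 44 lower in the spleen (adjusted p = 0.00188, and adjusted p = 0.229 with an estimated correlation). Ccr7, the receptor that guides DCs to lymph nodes, was 13.97 ± 0.28 in thymic CD103- cells against 7.96 ± 0.19 in macrophages (adjusted p = 4.17e-08), and higher by 2.99 ± 0.52 (adjusted p = 0.000136) in the spleen. Irf4 was higher by 5.81 and 4.73, Flt3 by 3.07 and 2.83, Zbtb46 by at least 2.41 and 2.32, and Ccr2 by 7.01 and 4.60. The largest thymic differences included Ccl22 (8.37), the thrombin receptor F2r (8.27), the protease Adam8 (7.76), the sterol hydroxylase Cyp7b1 (at least 5.70) and the checkpoint receptor Havcr2 (7.37). In the spleen they included Tnfsf9 (7.44), Acod1 (Irg1, 6.17), the deiminase Padi2 (at least 4.61) and the growth factor receptor Kdr (5.72). Pan conventional DC markers were higher for 8 of 9 in both organs, over all genes and adjusted over the list alone for 8 and 8 (adjusted p = 0.0213 and 0.0167 with an estimated correlation). The maturation list was higher for 20 of 23 in the thymus (20 and 1 adjusted over the list alone; adjusted p = 2.76e-09, and adjusted p = 0.147 with an estimated correlation) and for 17 in the spleen (17 and 2 adjusted over the list alone; adjusted p = 1.11e-06, and adjusted p = 0.156 with an estimated correlation).

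Lower in CD103- cells than in macrophages were, beside Cd163, Fcgr1a (-5.17 in the thymus, -4.57 in the spleen), C1qa (-2.67, -5.79) and, in the spleen, Mertk (-2.56) and the scavenger protein Cd5l (-11.07). In the thymus Mertk (-0.53, adjusted p = 0.305) did not pass, and Cd14 was higher by 1.39. In the spleen Cd14 was called at 0.80, but not without CD103- replicate 1 (0.32, adjusted p = 0.507) or either macrophage replicate (adjusted p = 0.0914 and 0.187). The macrophage arrays of both organs also carried neutrophil genes, and the splenic ones erythroid genes. Such genes may stand among the macrophage signature genes, which were not screened for them. The neutrophil gene S100a8 was 17.50 in thymic and 16.36 in splenic macrophages, and it was lower in CD103- cells (-11.77 or below, -10.62 or below), as were S100a9 (-11.95, -11.65 or below) and the granule gene Ngp (-10.30 or below, -9.13 or below). Neutrophil markers were lower for 7 of 12 in the thymus and 9 in the spleen (7 and 9 adjusted over the list alone; adjusted p = 0.0213 and 0.00577 with an estimated correlation). Erythroid markers were lower for 8 of 9 in the spleen (9 adjusted over the list alone; adjusted p = 0.0167 with an estimated correlation), among them Hbb (-11.88). Lysosome genes were lower for 18 and 18 of 23 (18 and 18 adjusted over the list alone; adjusted p = 0.0325 and 0.0167 with an estimated correlation). Iron and haem recycling was lower for 11 and 11 of 12 (11 and 11 adjusted over the list alone; adjusted p = 0.0325 and 0.0167 with an estimated correlation). Fixed macrophage markers were lower for 15 of 22 in the thymus (1 and 16 adjusted over the list alone; adjusted p = 5.97e-07, and adjusted p = 0.215 with an estimated correlation) and for 20 in the spleen (1 and 20 adjusted over the list alone; adjusted p = 0.0487 with an estimated correlation). Called clusters numbered 4533 higher and 4263 lower in the thymus, and 4891 higher and 4430 lower in the spleen.

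The cDC2 to cDC1 contrast set the scale for the DC subsets. Thymic cDC2 exceeded cDC1 in Sirpa (9.05 ± 0.44, adjusted p = 8.43e-11), Il22ra2 (9.71), the selenium carrier Selenop, printed as Sepp1 (9.09), Csf1r (at least 7.72), the clotting factor gene F13a1 (at least 7.42) and Plau (at least 7.55). Splenic cDC2 exceeded cDC1 in Sirpa (9.49 ± 0.44, adjusted p = 3.51e-11), the adhesion molecule Cadm3 (8.97), Cd4 (8.94), Ptgs2 (8.73) and Irf4 (4.36). Lower in cDC2 were Xcr1 (-10.92 or below in the thymus, -8.21 in the spleen), Clec9a (-10.29, -8.08), Gcsam (-9.53, -8.61), the peptidase Anpep (-6.81 or below, -8.21) and Irf8 (-5.20, -5.81). Of 15 cDC1 markers, 13 were lower in the thymus and 15 in the spleen (14 and 15 adjusted over the list alone; adjusted p = 0.00396 and 0.00555 with an estimated correlation). Cell cycle genes were higher for 9 of 29 in the thymus (9 adjusted over the list alone; adjusted p = 2.76e-05, and adjusted p = 0.181 with an estimated correlation) and for 13 in the spleen (15 adjusted over the list alone; adjusted p = 1.76e-06, and adjusted p = 0.164 with an estimated correlation). Calls numbered 1566 higher and 1608 lower in the thymus, and 1823 higher and 1903 lower in the spleen. Across genes, thymic and splenic differences had a Pearson's r of 0.612 here, against 0.670 for CD103- cells with cDC1 and 0.809 with macrophages.

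The last question was how each population differed between the organs, with isolation methods that differed for the DCs. Ccl22 was higher by 10.35 ± 0.32 (adjusted p = 1.12e-12) in thymic cDC1 and by 10.67 ± 0.32 (adjusted p = 6.68e-13) in thymic cDC2, and Ccl17 by 8.56 in cDC1 and 7.88 in CD103- cells. Thymic cDC1 were higher in Irf4 (3.31) and Ccr7 (2.64), and lower in the thrombospondin Thbs1 (-6.91) and the ATP receptor P2rx7 (-6.65). Their maturation list gave 17 higher and 1 lower of 23 (17 and 1 adjusted over the list alone; adjusted p = 2.18e-20, and adjusted p = 0.0547 with an estimated correlation). Thymic cDC2 were higher in the Langerhans cell lectin Cd207 (at least 9.92), apolipoprotein Apoe (8.56), Cd163 (at least 5.61) and Cd14 (3.83), and lower in Faim2 (-6.80 or below), Treml4 (-7.54), Cxcr3 (-7.01 or below), Hes1 (-5.82) and Xcr1 (-3.56 or below). Thymic CD103- cells were higher in Cd207 (at least 7.76), Apoe (7.20), Apoc1 (at least 5.48), C1qa (3.40) and Mertk (3.11), and lower in Acod1 (Irg1, -7.01), Nos2 (-6.68), Slpi (-5.14) and Flt3 (-2.47). Macrophage markers were higher in the thymus for 16 of 22 in cDC2 (16 and 1 adjusted over the list alone; adjusted p = 4.71e-12, and adjusted p = 0.119 with an estimated correlation) and for 15 in CD103- cells (15 and 3 adjusted over the list alone; adjusted p = 2.2e-12, and adjusted p = 0.0747 with an estimated correlation). In CD103- cells the lysosome list gave 13 higher and 1 lower of 23 (17 and 1 adjusted over the list alone; adjusted p = 0.0284 with an estimated correlation), and efferocytosis 13 higher and 3 lower of 21 (16 and 3 adjusted over the list alone; adjusted p = 0.0235 with an estimated correlation). The cDC2A markers were lower in the thymus for 4 of 7 in cDC2 and 3 in CD103- cells (4 and 4 adjusted over the list alone; adjusted p = 0.0237 and 0.0396 with an estimated correlation).

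T cell and thymocyte markers moved with the organ in all 4 populations. Of 18 members, 13 were higher in thymic than splenic cDC1, 12 in cDC2, 9 in CD103- cells and 11 in macrophages, with 1 lower, in CD103- cells (13, 14, 10 and 12 higher adjusted over the list alone). Camera called the list in all 4, with an adjusted p of 2.02e-13, 1.25e-11, 6.48e-06 and 8.22e-10. With an estimated correlation the adjusted p was 0.0547, 0.0456, 0.0753 and 0.0225, so the calls in cDC2 and macrophages held. Thymic macrophages were higher in the scavenger receptor Stab1 (at least 7.69), the serotonin receptor Htr1b (7.23), the elastase Mmp12 (6.93), Ccl17 (6.63) and Clec10a (4.59), and lower in Hbb (-11.31) and Ccr3 (-10.57 or below). Their interferon list was lower for 17 of 24 (19 adjusted over the list alone; adjusted p = 0.00656 with an estimated correlation). Markers of B cells (9 of 10 lower, 9 adjusted over the list alone), NK cells (7 of 9, 8 adjusted over the list alone) and erythroid cells (8 of 9, 8 adjusted over the list alone) were lower in thymic macrophages too. All 3 kept their call (adjusted p = 0.0427, 0.00758 and 0.00421 with an estimated correlation). Higher and lower in the thymus were 1552 and 1248 clusters for cDC1, 1852 and 1530 for cDC2, 1651 and 1222 for CD103- cells, and 1441 and 1745 for macrophages. With an array left out, the calls fell as far as 1736 for cDC1 (without thymus cDC1 replicate 2), 1633 for CD103- cells (without thymus CD103- replicate 2) and 2090 for macrophages (without spleen macrophage replicate 2).

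Markers of other cell types and genes of RNA stress and dissociation were also called between the organs. In thymic cDC1, B cell markers gave 6 higher and 1 lower of 10 (8 and 1 adjusted over the list alone; adjusted p = 0.000249, and adjusted p = 0.329 with an estimated correlation). Epithelial and stromal markers gave 7 higher and 0 lower of 14 (7 and 0 adjusted over the list alone; adjusted p = 0.000742, and adjusted p = 0.0547 with an estimated correlation) there. The NK cell list gave 0 higher and 2 lower of 9 (0 and 2 adjusted over the list alone; adjusted p = 0.00562, and adjusted p = 0.129 with an estimated correlation). In CD103- cells it gave 0 higher and 2 lower of 9 (0 and 2 adjusted over the list alone; adjusted p = 0.00698, and adjusted p = 0.114 with an estimated correlation). B cell markers gave 0 higher and 2 lower of 10 (0 and 2 adjusted over the list alone; adjusted p = 0.000552, and adjusted p = 0.272 with an estimated correlation) in CD103- cells. The stress list gave 2 higher and 9 lower of 16 (2 and 9 adjusted over the list alone; adjusted p = 0.00699, and adjusted p = 0.452 with an estimated correlation) in cDC2. In macrophages it gave 1 higher and 5 lower of 16 (1 and 5 adjusted over the list alone; adjusted p = 0.00839, and adjusted p = 0.333 with an estimated correlation). None of these 7 calls held with an estimated correlation.

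Further lists of this kind were called between populations, and of those given here only the platelet list held with an estimated correlation. Against cDC1, the T cell and thymocyte list gave 1 higher and 6 lower of 18 (1 and 8 adjusted over the list alone; adjusted p = 0.00748, and adjusted p = 0.193 with an estimated correlation) in thymic CD103- cells. Epithelial and stromal markers gave 0 higher and 5 lower of 14 (0 and 5 adjusted over the list alone; adjusted p = 0.01, and adjusted p = 0.0594 with an estimated correlation). Neutrophil markers gave 3 higher and 0 lower of 12 (3 and 0 adjusted over the list alone; adjusted p = 0.0151, and adjusted p = 0.0577 with an estimated correlation), and in the spleen 3 higher and 0 lower of 12 (3 and 0 adjusted over the list alone; adjusted p = 0.032, and adjusted p = 0.0769 with an estimated correlation). Stress genes gave 7 higher and 0 lower of 16 (9 and 1 adjusted over the list alone; adjusted p = 4.95e-05, and adjusted p = 0.133 with an estimated correlation) in the thymus. In the spleen they gave 4 higher and 0 lower of 16 (4 and 0 adjusted over the list alone; adjusted p = 0.0307, and adjusted p = 0.444 with an estimated correlation). Against macrophages, stress genes gave 9 higher and 0 lower of 16 (9 and 0 adjusted over the list alone; adjusted p = 0.00225, and adjusted p = 0.363 with an estimated correlation) in thymic CD103- cells. In splenic ones B cell markers gave 1 higher and 6 lower of 10 (1 and 7 adjusted over the list alone; adjusted p = 0.0343, and adjusted p = 0.527 with an estimated correlation). NK cell markers gave 1 higher and 6 lower of 9 (1 and 6 adjusted over the list alone; adjusted p = 0.0084, and adjusted p = 0.108 with an estimated correlation) there. Platelet markers gave 0 higher and 4 lower of 5 (0 and 4 adjusted over the list alone; adjusted p = 0.00856, and adjusted p = 0.0487 with an estimated correlation).

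For cDC2 against cDC1, B cell markers gave 0 higher and 8 lower of 10 (0 and 9 adjusted over the list alone; adjusted p = 4.74e-07, and adjusted p = 0.126 with an estimated correlation) in the thymus. In the spleen NK cell markers gave 0 higher and 2 lower of 9 (0 and 2 adjusted over the list alone; adjusted p = 0.0197, and adjusted p = 0.175 with an estimated correlation). Stress genes gave 4 higher and 0 lower of 16 (5 and 0 adjusted over the list alone; adjusted p = 0.0138, and adjusted p = 0.448 with an estimated correlation) there.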

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

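The interaction test was fixed before the data were examined, while every test of admixture or carried-over RNA given here was chosen only after the result it bears on had been seen.

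The difference between CD103- cells and cDC2 differed between thymus and spleen for 823 clusters. Values are thymic minus splenic log2 differences. They are not bounded by background, although at least 1 of the 4 group means lay below 5.73 for Faim2, Apoc1, Mmp14, Cxcr3, Dtx1, Xcr1, Fcgr3a, Clec9a, Cldn1, Lyve1, RT1-M5, Clec4d, Kcnh5, Tmem63c, Cd163, Cxcl11, Cmklr1, C3ar1, Gda, Nos2, S100a4 and Slc11a1. The sizes of those depend in part on background signal, and Faim2, Cxcr3, Dtx1, Xcr1 and Clec4d lay below 5.73 in both thymic groups. RT1-M5, Kcnh5 and Apoc1 lay below it in both splenic groups, so their interactions reflect the thymic difference alone. More positive in the thymus were Faim2 (6.35), Apoc1 (6.31), Hes1 (4.80), Ttyh2 (4.78), Mmp14 (4.65), Cxcr3 (4.44), Dtx1 (3.63), C3 (3.60), Xcr1 (3.52), Ctsd (3.30), Fcgr3a (2.95), Clec9a (2.74) and Cx3cr1 (2.06). More positive in the spleen were the surface and secreted products Cldn1 (-7.23), Lyve1 (-6.80), Gjb2 (-5.70), RT1-M5 (-4.87), Clec4d (-4.68), Ccl22 (-4.52), Kcnh5 (-4.33), Tmem63c (-4.32), Cd163 (-4.11), Cxcl11 (-3.72), Cmklr1 (-3.54), Olr1 (-3.40), C3ar1 (-3.18), Il22ra2 (-3.03), Cd14 (-2.92), Clec7a (-2.86), Itgae (-2.30), Ly6c (-2.24) and Fcgr1a (-2.22). Within the cell they were Irg1 (Acod1, -6.70), Gda (-6.44), Nos2 (-5.63), S100a4 (-5.31), Slc11a1 (-4.72), Samsn1 (-3.61), Ifit3 (-3.00), Gbp2 (-2.83) and Tfec (-2.37). Clec12a (-1.57, adjusted p = 0.0452) lost its call without each array except thymus CD103- replicate 1, with an adjusted p up to 0.209 without thymus CD103- replicate 2.

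By list, the median interaction was 0.68 for cDC1 markers (adjusted p = 0.000901, and adjusted p = 0.274 with an estimated correlation), 0.57 for cDC2 markers (adjusted p = 0.00223, and adjusted p = 0.144 with an estimated correlation) and 0.53 for cDC2A markers (adjusted p = 0.0106, and adjusted p = 0.17 with an estimated correlation). It was 0.43 for MHC class II presentation (adjusted p = 0.0203, and adjusted p = 0.321 with an estimated correlation), 0.51 for lysosome genes (adjusted p = 0.00212, and adjusted p = 0.274 with an estimated correlation) and 0.90 for genes of RNA stress and dissociation (adjusted p = 0.000901, and adjusted p = 0.321 with an estimated correlation). It was -0.34 for plasmacytoid DC markers (adjusted p = 0.0203, and adjusted p = 0.274 with an estimated correlation), -0.35 for maturation and costimulation (adjusted p = 0.000678, and adjusted p = 0.321 with an estimated correlation), -0.84 for interferon response genes (adjusted p = 7.46e-06, and adjusted p = 0.144 with an estimated correlation) and -0.60 for T cell and thymocyte markers (adjusted p = 0.00131, and adjusted p = 0.274 with an estimated correlation). For iron and haem recycling it was -0.017, with a mean of -1.07 (adjusted p = 0.0359, and adjusted p = 0.327 with an estimated correlation). MHC class II presentation, iron and haem recycling, plasmacytoid DC and T cell markers also lost the call when an array was left out, with an adjusted p up to 0.151, 0.159, 0.0845 and 0.0555. No list kept its call with an estimated correlation.

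Macrophage and monocyte markers were higher in CD103- cells than in cDC2, and admixed HIS36+ macrophages could raise them. In the thymus 12 bright macrophage markers implied a median macrophage share of 7.32% (from -2.48% to over 100% by gene, quartiles 2.04% and 13.9%). Of the 25 higher members, 16 lay over 1 log2 above a mixture at that share. In the spleen 14 such markers implied 1.54% (0.01% to 26.9%, quartiles 0.76% and 9.64%), with 17 of 26 above. The share is a median over members of the same lists, so some members lie above it by construction. However, 10 thymic and 6 splenic members were no brighter in macrophages than in CD103- cells, which argues against admixed macrophages as their only source. This count does not decide for the other members above the mixture. The mean of the macrophage markers differed between the splenic CD103- arrays (9.271 and 10.179), while that of the monocyte markers hardly did (12.285 and 12.245). At these shares Cd5l came out short of the mixture (-3.91 log2 in the thymus, -5.08 in the spleen), as did splenic Cd163 (-3.73). Thymic Cd163 was lower than in cDC2 themselves. With no signal counted from cDC2, the levels of both genes allow at most 0.55% in the thymus and 0.09% in the spleen. At those shares 7 of the 9 remaining thymic members and 8 of the 9 splenic ones lay over 1 log2 above the mixture, or above both cell types. Cd163 and Cd5l gave the lowest shares of the bright markers, so markers with higher shares lie above that mixture by construction, though not by a set amount. Cd163 is also the antigen of the macrophage sort. For these members the values therefore argue only against macrophages that carry Cd163 and Cd5l at the level of the HIS36+ sort. Macrophages with less of both stay open as untested. Admixture of HIS36+ macrophages stays open for Cd36 in both organs and for thymic Cd5l, which lay within 1 log2 of that mixture. Of 21 monocyte markers 13 were called higher in each organ. S100a8, S100a9 and thymic Vcan were among those that were not. In CD103- cells and cDC2, S100a8 was 4.81 and 4.3 in the thymus, and 4.38 and 4.47 in the spleen. S100a9 was 6.08 and 5.28, then 5.51 and 5.02. Vcan was 4.49 and 4.33 in the thymus, and called higher in the spleen (7.46 and 4.31). The level of these genes in monocytes was not measured, so they do not decide on admixed monocytes. Admixed monocytes, of which there was no sample, and a difference between the populations themselves stay open as untested.

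Of 15 cDC1 markers 6 were higher in splenic cDC2 than in splenic CD103- cells and 2 lower (9 and 2 adjusted over the list alone; adjusted p = 1.45e-05, and adjusted p = 0.0602 with an estimated correlation), and cDC1 carried over into the cDC2 sort might give the former. From 5 other bright cDC1 genes the implied share of cDC1 was 0.35% (0.26% to 1.23%), and of the 5 members that differed by over 1 log2, 3 (Xcr1, Clec9a and Gcsam) lay within 1 log2 of the level it gives, which is consistent with carry-over. The other 2, Tlr3 and Wdfy4, lay 1.31 and 1.66 log2 above it, which argues against carry-over as their only source. At the highest share Tlr3, Wdfy4 and Batf3 (whose difference was 0.99) lay 0.77 (SE 0.37), 1.57 (SE 0.35) and 0.89 (SE 0.25) log2 above the level, which argues against carry-over as the only source of Batf3 too, while Xcr1, Clec9a and Gcsam came out short (-1.87, -1.78 and -2.29), so that share is too high for them. Low expression of these genes by cDC2 themselves stays open as untested, and so does a difference by organ.

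T cell and thymocyte markers were higher in thymus than in spleen in every population, though the list lost its call in cDC1 (adjusted p = 0.0547 with an estimated correlation) and in CD103- cells (adjusted p = 0.0753 with an estimated correlation). RNA of a shared thymocyte source, carried in all sorts, would keep the increments of the genes in the same ratio from sort to sort. The ratios were taken over the members called higher in both sorts compared (11 in cDC2, 9 in CD103- cells and 11 in macrophages). Against cDC1, the log2 ratio of increments had an SD over genes of 0.73 in cDC2, beside an error of 0.71. With members without a called increment left out and an error that large, this value does not decide on a shared source in cDC2. The SD was 1.83 in CD103- cells (error 0.45, from -2.50 for Themis to 2.86 for Cd8b) and 2.27 in macrophages (error 0.52, from -4.37 for Tcf7 to 3.36 for Cd8a), which argues against a shared source as the only one there. Expression by the sorted cells, and the isolation methods that differed by organ, stay open as untested.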

How the results depend on the processing

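All settings except the background of olfactory receptor genes were fixed before the data were examined, and none of the tests in this part was chosen after a result was seen. No called direction of a named gene, list or signature was reversed in any setting. With the series matrix in place of the log2 table all values were the same. When an array was left out, the remaining array of its group was assumed to vary like the other groups, and 872 of 6656 called gene comparisons lost their call while 8 were gained. Fewer arrays widen the error by construction. With only the arrays of the groups compared, 94 of 1590 gene calls were lost and 7 gained. Array weights, the variance trend, scaling and the replicate block (2469 calls in the thymus, 2187 in the spleen, 909 in the interaction and 946 shared by both organs) moved no count by more than 1.5 times, and a 2-fold minimum left 1715 thymic and 1574 splenic calls of CD103- cells against cDC2.

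With an estimated inter-gene correlation, 101 of 187 list calls were lost. Some were lost although the estimate lay below the preset 0.01. For thymic CD103- cells these included neutrophil markers against cDC2 (estimate -0.005, camera adjusted p = 0.0352 and then 0.0902). They also included cDC2B and DC3 markers against macrophages (estimate -0.023, camera adjusted p = 0.0138 and then 0.082). A higher correlation therefore cannot be the cause for these lists, and what else differed between the settings was not tested. For pattern recognition receptors in thymic CD103- cells against cDC2 (estimate 0.009), the camera adjusted p went from 4.81e-14 to 0.000669. Calls lost in this setting, here and in the sections above, can therefore not be put down to correlation alone. In the thymus the lists called fell from 19 to 11 for CD103- cells against cDC2, from 20 to 12 against cDC1, from 10 to 4 against macrophages, and from 15 to 5 for cDC2 against cDC1. In the spleen they fell from 16 to 10 for CD103- cells against macrophages (9 with the filter on dim clusters) and from 12 to 5 for cDC2 against cDC1. Between the organs they fell from 11 to 0 for cDC1 (lowest adjusted p 0.0547, with 7 unadjusted and 13 by fry), from 9 to 2 for cDC2, from 13 to 3 for CD103- cells and from 18 to 10 for macrophages. For the interaction they fell from 11 to 0 (lowest adjusted p 0.144, with 3 unadjusted and 4 by fry).

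The filter on dim clusters raised all distances, since it drops clusters that hardly differ. In the thymus CD103- cells then lay 0.854 from cDC2, 1.305 from cDC1 and 1.637 from macrophages, and cDC2 lay 1.079 from cDC1. In the spleen the values were 0.86, 1.284, 1.653 and 1.145, and quantile normalization gave 1.272 for CD103- cells and macrophages.

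With an array left out, CD103- cells against cDC2 gave 1520 to 1660 calls in the thymus, where all arrays gave 2377 (1520 without cDC2 replicate 1, 1531 without cDC2 replicate 2 or CD103- replicate 2) and 1388 to 1527 in the spleen, where all arrays gave 2092 (1388 without cDC2 replicate 2). Calls in opposite directions numbered 22 to 47, and 50 with all arrays (22 without spleen CD103- replicate 1, 27 without spleen cDC2 replicate 2, 31 without thymus cDC2 replicate 2). Between the organs, cDC1 gave 1736 to 2228 calls, and 2800 with all arrays (1736 without thymus cDC1 replicate 2), CD103- cells 1633 to 2051, and 2873 with all arrays (1633 without thymus CD103- replicate 2, 1836 without spleen CD103- replicate 1) and macrophages 2090 to 2397, and 3186 with all arrays (2090 without spleen macrophage replicate 2). These counts may include clusters that were not called with all arrays. Distances of thymic CD103- cells ran from 0.704 to 0.713 to cDC2, from 1.004 to 1.075 to cDC1 and from 1.263 to 1.323 to macrophages, with 0.849 to 0.898 between cDC2 and cDC1. In the spleen they ran from 0.709 to 0.725, from 1.005 to 1.053, from 1.298 to 1.331 and from 0.917 to 0.941.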

Other observations

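No test in this part was chosen after its result was seen, but Lyve1 was picked after its values were seen. The fixed macrophage markers gave 14 higher and 1 lower of 22 in thymic CD103- cells against cDC2 (15 and 1 adjusted over the list alone), with a median of 2.06. Against this direction, the log2 differences of CD103- cells minus cDC2 were -3.29 for Cd163, -3.86 for F13a1 and -2.40 for the hyaluronan receptor Lyve1, each called by limma. In the spleen Lyve1 was higher in CD103- cells (at least 4.24). Haem oxygenase Hmox1 was higher in thymic CD103- cells (2.86).

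Against cDC1, B cell markers were lower in thymic CD103- cells for 8 of 10 members (8 adjusted over the list alone; adjusted p = 3.39e-06, and adjusted p = 0.133 with an estimated correlation), and plasmacytoid DC markers were higher in splenic CD103- cells for 10 of 13 (11 adjusted over the list alone; adjusted p = 1.29e-12, and adjusted p = 0.00144 with an estimated correlation). Thymic macrophages differed from splenic ones in further lists. Monocyte markers gave 2 higher and 11 lower of 21 (2 and 11 adjusted over the list alone), pan conventional DC markers 0 higher and 5 lower of 9 (0 and 8 adjusted over the list alone), pattern recognition receptors 1 higher and 8 lower of 19 (1 and 9 adjusted over the list alone) and efferocytosis and lipid efflux 11 higher and 3 lower of 21 (14 and 3 adjusted over the list alone). With an estimated correlation the adjusted p of these 4 lists was 0.0153, 0.0153, 0.0225 and 0.0225.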
